A study of Rattus norvegicus with 4 samples.

How the data were processed

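Total RNA of neonatal rat ventricular myocytes (2 libraries with DMSO vehicle, 2 with 3 µM TMP195 for 48 h) was purified on columns and made into sequencing libraries with an Ovation RNA-Seq kit, per the labels' protocols. Cufflinks is the tool named in the submitters' processing notes. Its version, the aligner, the genome build and the annotation are not given in the sources used here.

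The main table holds 17147 gene names with a value per library. These deposited values are a signal rather than raw reads: the authors' estimated fragment counts, scaled by a common factor for each library. This was read from the values, since 99.27 to 99.46% of those up to 10000 fragments were whole multiples of a fixed step within 0.1 fragment, and the rest were fractional. The step was 0.948 and 1.05 for the vehicle libraries and 0.879 and 0.959 for the TMP195 libraries. Divided by its step, the libraries held 12902269, 11768452, 14232152 and 13097078 fragments in that order, with 12583 to 12800 genes above 0 and 5.70 to 6.16% of the total in the 10 largest genes. A gene with a value of 100 thus rests on about 100 fragments. A further table holds FPKM values that the authors deposited for 10673 genes. They were proportional to the main table within 0.001 on the log2 scale for 96.8% of 8824 genes compared, so they were not tested again. It also holds a deposited p-value for each gene except 56. Recomputing it showed that the authors' p-value is an unadjusted two-sided Welch test on the FPKM values. The authors' sheets of higher and lower genes add the ratio of mean FPKM with TMP195 to mean FPKM with vehicle.

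Samples were grouped by their titles and treatment labels. Gene names were used as the table gives them: 14500 matched a symbol and 2206 an older synonym in the RefSeq gene table of assembly GRCr8, which was used for names alone. A list member was also matched through an older name that belongs to no other gene. There were 25 names that a spreadsheet had turned into dates and 4 entries with repeated names. Col1a2 is listed at 0 in all 4 libraries beside a vehicle mean of 68210 for Col1a1, so a 0 in this table need not mean an absent transcript, and Col1a2 was not tested. No coordinates are given because the build is not given in the sources used here.

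The replicates were checked for duplicate libraries. A chi-square test of the values divided by their step gave 4.90 per gene between the vehicle libraries and 5.98 between the TMP195 libraries, with 32.4% and 32.1% of genes at p under 0.05, so each was counted as a separate library.

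The design fixed before the data were examined called for a count model, with limma-trend on log2(value + 1) if the table held no counts. Because the values turned out not to be raw counts, limma 3.58.1 in R 4.3.3 was the main test. Genes with a mean value of 1 or more were kept, 12689 in all, with no further scaling, because the authors' values were already scaled. The model had treatment as its only term and an adjusted p (Benjamini-Hochberg) under 0.05 as its threshold. It had 2 residual and 27.4 prior degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The table gives no strand, so overlapping and antisense genes cannot be told apart.

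The genes named in the report follow a rule set before the data were examined. First came genes with an adjusted p under 0.05, a full gene symbol and both TMP195 libraries on the same side of both vehicle libraries. They also had a log2 of the mean CPM of 1 or more. Of these, the 10 with the largest log2 fold change in each direction were named. The plan had used normalised CPM for the sides and the mean of log2 CPM, whereas the sides were judged on the deposited values. Second, from each gene list up to 4 tested members with the smallest p were named. Last, Hdac4, Hdac5, Hdac7 and Hdac9 were named. Some genes that the rule selects are not reported here. Further members of the lists are given as examples and were chosen after their values were seen, as were the symbol families and Gsta5 in the closing section.

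Gene lists and marker lists of other cell types were also fixed beforehand. The 38 lists with 5 or more tested genes were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. With 2 residual degrees of freedom, that estimate is imprecise. In that mode camera also refers its statistic to these 2 degrees of freedom, so few lists could pass whatever their correlation. The red cell markers had too few tested genes for a test. Camera was planned on log2 CPM and was run on log2(value + 1) with the rest of the fit. The rotation test fry was run as a description only and its results are not given here.

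The fit was tested on simulated data drawn for the real genes with a dispersion of 0.0035. Over 12658 genes, it recovered 32% of 50 genes changed by 1.25-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. There were 6 false calls among 163 (3.68%). With no gene changed, it called 0 genes and 0 of 38 lists. Every gene was drawn with the same dispersion, so false calls from genes that vary more than others were not measured. This simulation has less spread at low values than real cultures may have. Its genes were drawn independently of each other, so it could not show false list calls that arise from correlated genes. The changed genes were drawn above a higher mean value than the filter of the fit, so recovery at the lowest values was not measured.

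Alternatives were a pseudocount of 0.1, no filter on low values, scaling by the median of ratios or by the library total, limma-voom, the replicate number as a block, each library left out in turn and, chosen after seeing the data, a mean value of 10 or more or of 100 or more. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading tables, checks and plots.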

Results

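RNA from neonatal rat ventricular myocytes was sequenced after 48 h with TMP195 or with its solvent. These are primary heart muscle cells isolated from the ventricles of newborn rats, grown here without serum. TMP195 is a small molecule that occupies the deacetylase site of the class IIa histone deacetylases, and it was given at 3 µM. There were 2 libraries with DMSO vehicle and 2 with TMP195. The deposited values corresponded to 12902269 and 11768452 fragments for the vehicle libraries and to 14232152 and 13097078 for the TMP195 libraries. The labels do not say whether the libraries came from separate cultures. The limma p-values below thus rest on the spread between these 4 libraries, which may be technical, taken mostly as a trend across genes. Camera with its preset correlation, Fisher's exact test and Cochran's Q compare genes with each other, so their p-values measure no spread between cultures. Log2 values correlated across genes at 0.993 between the vehicle libraries, at 0.994 between the TMP195 libraries and at 0.975 to 0.977 between the treatments. The first principal component held 77.5% of the variance and separated the treatments.

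The single comparison of the study, TMP195 against vehicle, asks which transcripts change when the class IIa enzymes are inhibited in cardiac myocytes, with oxidative stress as the study's particular concern. With TMP195 19 of 32 genes of the NRF2 antioxidant response rose, 26 of 29 of the integrated stress response, 14 of 19 of protein folding in the endoplasmic reticulum and 20 of 32 of fatty acid oxidation. Of genes of the cell cycle 26 of 32 fell, as did 22 of 35 of the extracellular matrix and several ion channel and cardiac transcription factor genes. Camera called these lists with its preset correlation, and none of them with an estimated correlation (adjusted p from 0.168 to 0.413). The latter has little power with 2 residual degrees of freedom, and the preset value was not measured here, so neither settles the list calls. Srxn1, which encodes sulfiredoxin, the enzyme that restores hyperoxidised peroxiredoxins, had the smallest p of all genes. It rose 3.29-fold (95% confidence interval 2.98 to 3.64), from 2050 ± 37.1 to 6753 ± 6.81 (SD, n = 2 each), with a limma adjusted p of 6.22e-17. Of 12689 genes tested with limma, 1260 were higher and 1313 were lower at an adjusted p under 0.05. Most of these changes were small. The median log2 fold change was 0.42 among the genes that rose and -0.55 among those that fell, and 86 genes rose and 236 fell by 2-fold or more. With 1 library left out, limma called 0 genes without vehicle 1, without vehicle 2 or without TMP195 2, and 322 higher and 406 lower without TMP195 1, while 2589 to 2841 genes had an unadjusted p under 0.05. When only genes with a mean value of 100 or more were tested, a setting chosen after seeing the data, the same 4 fits called 971 to 1086 genes higher and 944 to 1082 lower, but there limma replaced the spread of each gene by the trend across genes.

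**Figure D1:**
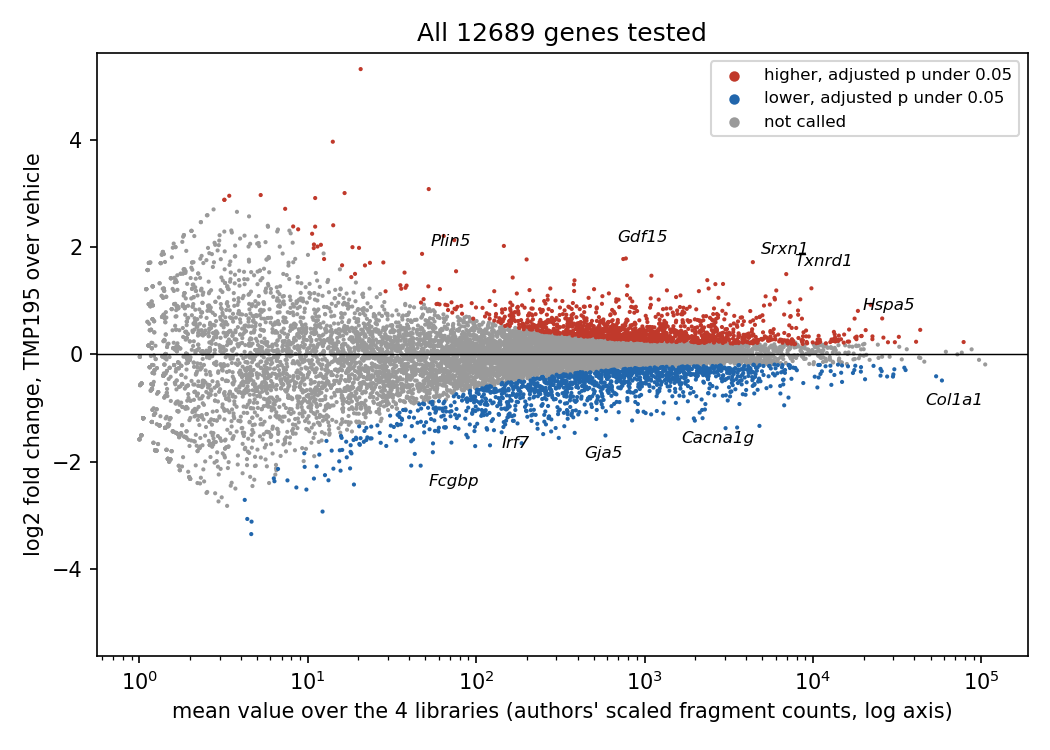
Each point is 1 of 12689 genes, with its mean value over the 4 libraries (the authors' scaled fragment counts, log axis) on the x axis and its log2 fold change of TMP195 over vehicle on the y axis. Red points are the 1260 genes called higher and blue points the 1313 called lower by limma; the calls reach closer to 0 at high mean values, where the spread between libraries was small.

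Several of the 10 largest increases were in members of the lists tested below. Srxn1 and Osgin1 are listed NRF2 targets, Gdf15 is an integrated stress response gene and Plin5 a fatty acid oxidation gene. No shared theme was tested among the 10 themselves. Gdf15, a secreted stress cytokine, rose 3.45-fold, from 344.6 ± 18.2 to 1205 ± 249.6 (SD, n = 2 each; limma adjusted p = 1.64e-12). Osgin1, a growth inhibitor induced by oxidative stress, rose 3.43-fold (limma adjusted p = 3.43e-12). Plin5, a coat protein of lipid droplets in oxidative tissues, had a log2 fold change of 1.87 (SE 0.35), and Soat2, which esterifies cholesterol, one of 1.71 (SE 0.45), both at low values. Cdh17 (2.13), Eid3 (2.02), B3gat1 (1.77), which makes the HNK-1 carbohydrate, and Card9 (1.55), an adaptor of innate immune signalling, were the other large increases with Srxn1 and Gabpb1l. Gabpb1l had a log2 fold change of 2.21 (SE 0.32), which is uncertain because its name marks it as a near copy of Gabpb1 and fragments could be divided between them. The largest decreases were in Fcgbp (-2.08), Scara5 (-2.07), a ferritin receptor, Dlg2 (-1.86), a membrane scaffold, and Melk (-1.83), a kinase of dividing cells. They were followed by Olfml2a (-1.71), Zfp483 (-1.71), Efemp1 (-1.70), a fibulin of the matrix, Ston2 (-1.66), Smtnl2 (-1.66) and Met (-1.65), the receptor of hepatocyte growth factor. These 10 genes had limma adjusted p between 6.17e-08 and 0.00671.

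The genes of the inhibited enzymes themselves moved little. Hdac4 had a log2 fold change of 0.07 (SE 0.15, limma adjusted p = 0.809) and Hdac9 of 0.25 (SE 0.17, limma adjusted p = 0.324), neither of which passed the test. Hdac5 rose 1.27-fold, from 853.3 ± 147.7 to 1074 ± 18.4 (SD, n = 2 each; limma adjusted p = 0.0151), a call that ended when genes of low value were kept in the test (adjusted p = 0.0764). Its log2 fold change of 0.34 was 0.52 without vehicle 1 and 0.16 without vehicle 2. Hdac7 was not analysed here. Among all 13 genes of class IIa enzymes and their partners, 2 rose and 2 fell, also when adjusted over the list alone. Hdac5 and Mef2d (0.21) were higher and Mef2a (-0.25) was lower. Mef2a and Mef2d are the transcription factors that class IIa enzymes bind. The Mef2d call was lost with a pseudocount of 0.1, without the filter on low values, with scaling by library total, with limma-voom and with the replicate number as a block (adjusted p from 0.0556 to 0.113). Camera did not call the list (adjusted p = 0.941). Its median of 0.02 and its mean of 0.03 lay above 0 while camera gave the direction as down, and the median was -0.01 with scaling by library total. Sirt2 (0.35) and Sirt5 (0.27) rose among 11 other deacetylase and sirtuin genes (camera adjusted p = 0.730), and 9 did not pass the test. The same 2 passed when adjusted over the list alone, and Sirt5 was lost under the same 5 settings as Mef2d (adjusted p from 0.0531 to 0.0715). Of 17 muscle genes known as MEF2 targets, 5 rose and 4 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.941; median -0.03, mean 0.03, direction up). Nr4a1, an orphan nuclear receptor, rose 1.81-fold and Mb, which encodes myoglobin, rose with a log2 fold change of 0.33, while Myom2, a protein of the sarcomere's M band, had one of -0.52 (limma adjusted p = 1.99e-06).

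Genes that NRF2 induces against oxidants and electrophiles rose together. Of 32 tested, 19 rose, 1 fell and 12 did not pass the test, and 21 rose and 1 fell when adjusted over the list alone. Because the study was about these genes, the list may have been chosen on these samples and is not independent evidence of its direction. Besides Srxn1, Txnrd1, a cytosolic thioredoxin reductase, rose 2.82-fold (from 3637 ± 163.6 to 10260 ± 443.0, SD, n = 2 each; limma adjusted p = 1.03e-15). Sqstm1, the autophagy receptor p62, rose with a log2 fold change of 1.23 (SE 0.07), and Hmox1, which degrades haem, with one of 1.19 (SE 0.07). The enzymes of glutathione synthesis Gclm (0.85) and Gclc (0.64), the cystine transporter Slc7a11 (0.99), the ferritin chains Ftl1 (0.92) and Fth1 (0.46), and Nqo1 (0.56) also rose. Gstm1, a glutathione transferase, fell (-0.27, limma adjusted p = 0.0201), and Prdx1 (0.15), Prdx6 (0.05) and Tkt (0.09) did not pass. The list median was 0.38 (camera adjusted p = 2.71e-16; adjusted p = 0.168 with an estimated correlation). The NRF2 gene itself, Nfe2l2, rose with a log2 fold change of 0.45 (SE 0.07). It was listed among 8 genes of the aryl hydrocarbon receptor, of which Cyp1b1 (0.63) and Nqo1 rose as well, the same 3 as when adjusted over the list alone. The receptor's targets Cyp1a1 (0.04) and Aldh3a1 (-1.11) did not pass (list median 0.32; camera adjusted p = 0.0189; adjusted p = 0.373 with an estimated correlation). That list was lost without each of the 4 libraries in turn, with adjusted p of 0.0583 to 0.177 and medians down to 0.10 without TMP195 2 and 0.17 without vehicle 1.

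Antioxidant enzymes outside that list and the enzymes that make reactive oxygen were not called as groups by camera. Of 22 other antioxidant genes, Prdx5 (0.35), Prdx3 (0.33) and Sod2 (0.22) rose. Gpx3 (-0.90, limma adjusted p = 9.09e-09), Sod3 (-0.63), Sepp1 (-0.45), Prdx4 (-0.44) and Gpx7 (-0.38) fell. The count was 3 up and 6 down when adjusted over the list alone (camera adjusted p = 0.721). Of 12 NADPH oxidase genes 0 passed the limma test, also when adjusted over the list alone (camera adjusted p = 0.840). Ncf1 had a log2 fold change of 0.31 (SE 0.12, limma adjusted p = 0.0576) and passed when only genes with a mean value of 10 or more were tested (adjusted p = 0.0483). Nox4 had -0.97 (SE 0.50, limma adjusted p = 0.180) at a vehicle mean of 28.5.

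Genes of the integrated stress response, the program that ATF4 drives when translation is restrained, gave the clearest group increase. Of 29 tested, 26 rose, 0 fell and 3 did not pass the test, and 27 rose and 1 fell when adjusted over the list alone. Trib3, a pseudokinase target of ATF4, rose 2.76-fold (from 582 ± 18.4 to 1617 ± 222.5, SD, n = 2 each; limma adjusted p = 2.29e-12). Atf4 itself (1.02) and Atf5 (1.31) rose, Ddit3, which encodes CHOP, rose 2.14-fold and Chac1, which degrades glutathione, 2.15-fold. So did the amino acid genes Slc3a2 (1.05), Asns (0.81) and Mthfd2 (0.88), and Sesn2 (1.08), a sensor of leucine. Psat1 (-0.25, limma adjusted p = 0.0514), Aldh1l2 (0.14) and Fgf21, which was near 0 in the vehicle libraries, did not pass. The list median was 0.87 (camera adjusted p = 4.73e-36; adjusted p = 0.168 with an estimated correlation). Of 19 endoplasmic reticulum chaperone and unfolded protein response genes 14 rose and 0 fell, and 14 rose and 1 fell when adjusted over the list alone. Dnajb9, a co-chaperone of BiP, rose 2.48-fold from 1680 ± 8.82 to 4174 ± 3.44 (SD, n = 2 each). Hspa5, which encodes BiP, rose 1.59-fold, and Manf (0.75), Herpud1 (0.55) and Xbp1 (0.35) rose with it (list median 0.35; camera adjusted p = 2.62e-10; adjusted p = 0.178 with an estimated correlation). Of 18 heat shock genes, 6 rose, Hspa1a (-0.75) fell and 11 did not pass, also when adjusted over the list alone. Hspb8 (0.65) and its cochaperone Bag3 (0.49) led, beside Hspd1 (0.31) and Hspe1 (0.32), the chaperonin of mitochondria. The list had a median of 0.12 (camera adjusted p = 0.0152; adjusted p = 0.413 with an estimated correlation) and was lost without vehicle 1 (adjusted p = 0.0548) and without vehicle 2 (adjusted p = 0.0780).

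Genes that carry fatty acids into oxidation rose. Of 32 tested, 20 rose, 0 fell and 12 did not pass the test, and 21 rose and 1 fell when adjusted over the list alone. Cpt1b, the muscle carnitine palmitoyltransferase, rose 2.08-fold (from 1788 ± 100.1 to 3711 ± 23.6, SD, n = 2 each; limma adjusted p = 9.35e-12). Hadhb (0.91), Ech1 (0.86), Acsl1 (0.70), Acadvl (0.65) and Cd36 (0.55) rose, while Cpt1a (0.00), Hadh (0.04) and Pdk4 (-0.54) did not pass. The list median was 0.41 (camera adjusted p = 8.62e-14; adjusted p = 0.185 with an estimated correlation). Of 38 respiratory chain genes 9 rose, by small amounts led by Cox6a2 (0.37), Sdhb (0.31), Uqcrc1 (0.27) and Ndufv2 (0.26), 0 fell and 29 did not pass (10 up when adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.00144; adjusted p = 0.483 with an estimated correlation). Of 17 genes of the TCA cycle 4 rose and 0 fell, also when adjusted over the list alone, among them Dld (0.39), Suclg1 (0.33) and Cs (0.23). That list had a median of 0.09, and of 0.15 without vehicle 2 (camera adjusted p = 0.0388; adjusted p = 0.613 with an estimated correlation). It was lost without vehicle 1 (adjusted p = 0.160), without TMP195 1 (adjusted p = 0.0585), with scaling by library total (adjusted p = 0.0724) and with limma-voom (adjusted p = 0.0792). It was also lost with the replicate number as a block (adjusted p = 0.0536) and when only genes with a mean value of 10 or more (adjusted p = 0.0606) or 100 or more (adjusted p = 0.133) were tested. Of 25 glycolysis genes 6 rose and 3 fell (7 and 4 when adjusted over the list alone; camera adjusted p = 0.639). Pfkfb3 (0.87), Pfkfb2 (0.64) and Hk2 (0.40) were higher, and Aldoc (-1.07), Ldha (-0.35) and Pfkm (-0.34) were lower.

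Some lipid synthesis genes fell, and most did not pass the test. Of 16 fatty acid synthesis genes 6 fell and 0 rose, and 6 fell and 1 rose when adjusted over the list alone. The desaturases Fads2 (-0.77), Scd (-0.41) and Fads1 (-0.40) fell, as did Fasn (-0.25), the fatty acid synthase. The list median was -0.22 (camera adjusted p = 0.0191; adjusted p = 0.373 with an estimated correlation; lost without vehicle 2, adjusted p = 0.0986). Of 25 cholesterol synthesis genes 5 fell and 0 rose (6 fell when adjusted over the list alone), among them Hmgcs1 (-0.39), Nsdhl (-0.46) and Srebf2 (-0.31), which encodes the pathway's transcription factor. This list had a median of -0.11 (camera adjusted p = 0.0199; adjusted p = 0.523 with an estimated correlation; lost without TMP195 2, adjusted p = 0.0751).

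Genes of DNA replication and mitosis fell. Of 32 cell cycle genes 26 fell, 0 rose and 6 did not pass the test, and 29 fell when adjusted over the list alone. Mki67, the gene of the proliferation marker Ki-67, fell to 0.471 times its vehicle level, from 2892 ± 77.7 to 1362 ± 72.5 (SD, n = 2 each; limma adjusted p = 1.12e-11). The replication genes Mcm5 (-1.39), Mcm3 (-1.12), Rrm2 (-1.08) and Top2a (-1.06) and the mitotic genes Ccnb2 (-1.13) and Plk1 (-1.11) fell. Aurka (0.07), Ccne1 (-0.08) and Pcna (-0.25) did not pass. The members of the list had a median of -0.92 (camera adjusted p = 1.56e-22; adjusted p = 0.168 with an estimated correlation). Markers of fibroblasts fell along with them: 8 of 13 were lower, with a list median of -0.47. Of 18 p53 target genes 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0701). Gadd45a (0.65), Tp53inp1 (0.87), Mdm2 (0.46) and Cdkn1a (0.37), which encodes the cyclin kinase inhibitor p21, were among those that rose.

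Extracellular matrix genes fell, and so did markers of the cells that make most matrix in the heart. Of 35 matrix genes 22 fell, 3 rose and 10 did not pass the test, also when adjusted over the list alone. Col1a1 fell to 0.713 times its vehicle level (from 68210 ± 2490 to 48640 ± 1411, SD, n = 2 each; limma adjusted p = 5.28e-06). Vcan (-0.86), Lox (-0.78), Timp2 (-0.75), Fbn1 (-0.53) and Col3a1 (-0.51) fell. Thbs1 (0.25) and Ctgf (0.23) were among those that rose, and Fn1 (-0.06), Postn (0.12) and Col4a1 (0.02) did not pass. The members of the list had a median of -0.41 (camera adjusted p = 1.35e-07; adjusted p = 0.373 with an estimated correlation). Of 13 fibroblast markers 8 fell and 0 rose, also when adjusted over the list alone, with S100a4 (-0.73), Tcf21 (-0.55) and Pcolce (-0.41) lower, while Dcn (-0.06) and Ddr2 (-0.05) did not pass (camera adjusted p = 1.75e-06; adjusted p = 0.202 with an estimated correlation). Of 13 smooth muscle and myofibroblast markers 7 fell and 0 rose, also when adjusted over the list alone. Acta2, smooth muscle actin, fell to 0.678 times its vehicle level and Mcam (-0.63), Cspg4 (-0.57) and Tagln (-0.48) fell (list median -0.48; camera adjusted p = 4.27e-04; adjusted p = 0.244 with an estimated correlation).

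Lists of markers of other cell types that a ventricle preparation can hold were not called by camera, which does not show that they stayed the same. Of 12 endothelial markers Kdr (-1.06), Tek (-0.68) and Eng (-0.29) fell and Flt1 (0.66) rose, with 1 up and 4 down when adjusted over the list alone (list median -0.33; camera adjusted p = 0.0994). Flt1 was lost with a pseudocount of 0.1 (adjusted p = 0.0515) and without the filter on low values (adjusted p = 0.103). Of 14 macrophage and leukocyte markers 0 passed the limma test, also when adjusted over the list alone (camera adjusted p = 0.721; Cd68 0.39, SE 0.22). Of 9 epicardial markers Krt18 (0.83) rose and Tbx18 (-0.59) fell, with 1 up and 2 down when adjusted over the list alone (camera adjusted p = 0.454). Of 9 glial and neuronal markers Tubb3 (-0.65) fell, also when adjusted over the list alone (camera adjusted p = 0.877; median 0.04, mean -0.11, direction down). Red cell markers were at low values, with a vehicle mean of 6.16 for Hba2 and 2.37 for Hbb.

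**Figure D2:**
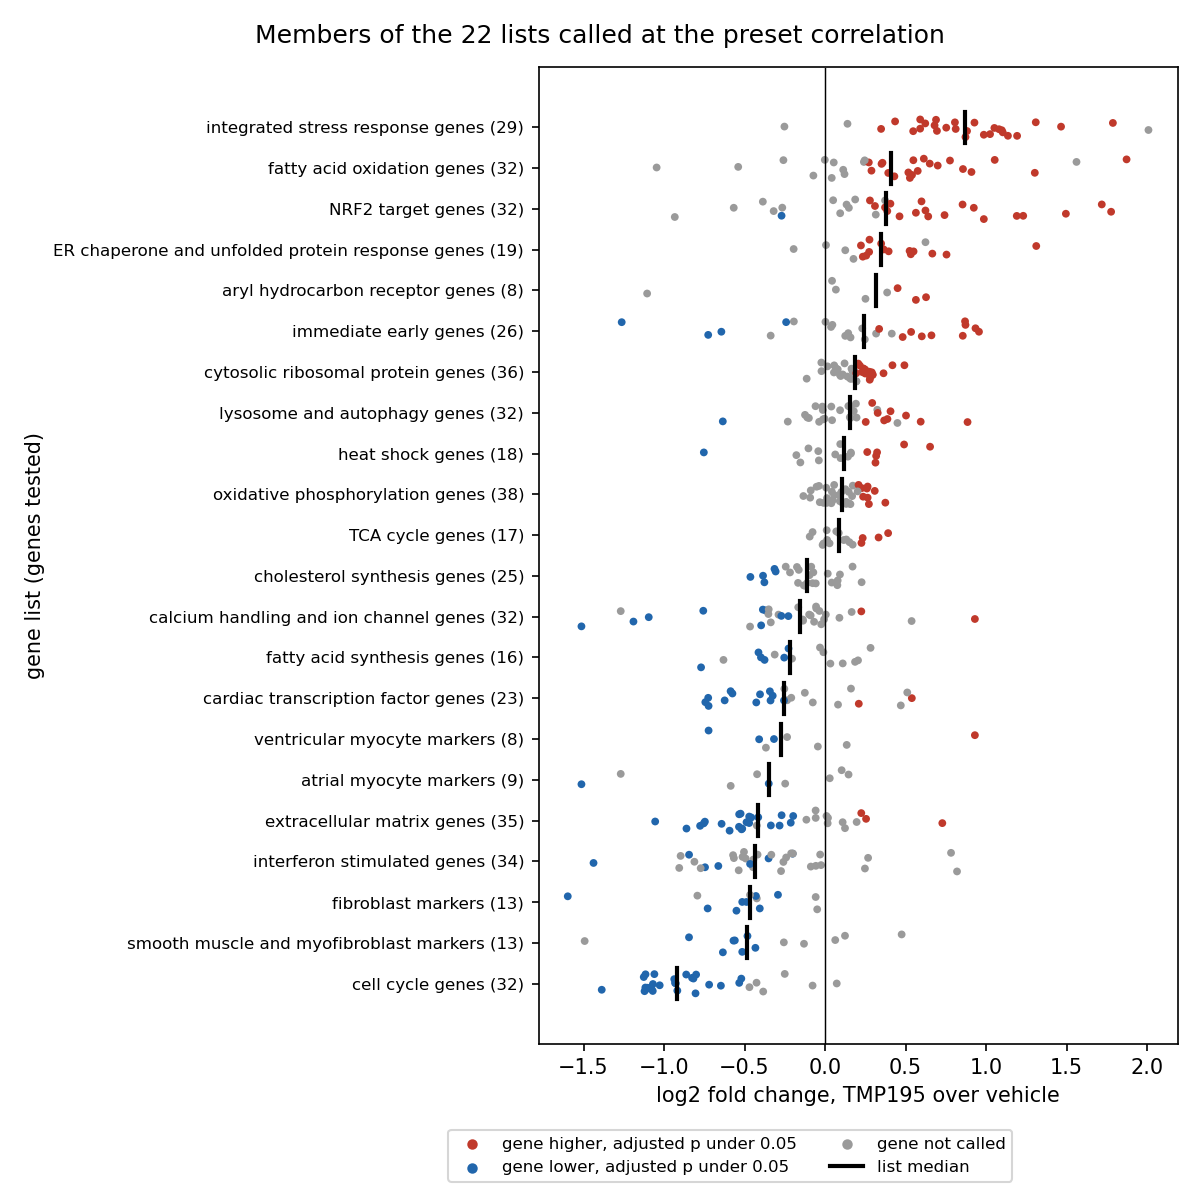
Each point is a gene of a list, with its log2 fold change of TMP195 over vehicle on the x axis; each line of points is 1 of the 22 lists that camera called with its preset correlation, sorted by their median (black bar), and the number of genes tested is in brackets. Members of the integrated stress response list lie to the right around a median of 0.87 and cell cycle genes to the left around -0.92, while the ribosomal and respiratory chain lists lie close to 0 with medians of 0.19 and 0.11.

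Among genes of calcium handling and ion channels and among cardiac transcription factor genes, more fell than rose, and most sarcomere genes did not pass the test. Gja5, the connexin of the fast conduction system, fell to 0.350 times its vehicle level (from 868.8 ± 28.4 to 303.6 ± 0.695, SD, n = 2 each; limma adjusted p = 1.36e-11). The T-type calcium channel Cacna1g (-1.19), the pacemaker channel Hcn4 (-1.09) and the potassium channel Kcnh2 (-0.76) fell, with the ryanodine receptor Ryr2 (-0.40) and the exchanger Slc8a1 (-0.27). Of 32 calcium handling and ion channel genes 9 fell, Kcne1 (0.93) and Gja1 (0.23) rose and 21 did not pass, with 10 down when adjusted over the list alone. Both increases were lost without the filter on low values (adjusted p = 0.0531 for Kcne1). Cacna1c (-0.06), Atp2a2 (-0.14) and Pln (-0.07) were among those that did not pass. The members of the list had a median of -0.15 (camera adjusted p = 4.08e-05; adjusted p = 0.202 with an estimated correlation). Of 23 cardiac transcription factor genes 12 fell and 2 rose, with 13 down when adjusted over the list alone. Tbx20 (-0.74), Srf (-0.73), Irx4 (-0.72), Tbx5 (-0.62), Irx3 (-0.59) and Nkx2-5 (-0.34) fell, Esrra (0.54) and Mef2d rose, and Gata4 (-0.13) did not pass. Members of the list had a median of -0.25 (camera adjusted p = 2.60e-05; adjusted p = 0.413 with an estimated correlation). Of 22 sarcomere genes 4 rose and 6 fell (4 and 9 when adjusted over the list alone). Mybpc3 (0.33) and Tnni3 (0.28) rose, Myom2, Myh7 (-0.41) and Nebl (-0.37) fell, and Myh6 (0.03), Tnnt2 (-0.10) and Actc1 (-0.19) did not pass. Their camera adjusted p was 0.127, and 0.0418 with limma-voom. Of 8 ventricular markers Irx4, Myh7 and Lbh (-0.32) fell and Kcne1 rose, also when adjusted over the list alone (list median -0.28; camera adjusted p = 0.0436; adjusted p = 0.459 with an estimated correlation). That call was lost without vehicle 1 (adjusted p = 0.177), vehicle 2 (adjusted p = 0.132) or TMP195 1 (adjusted p = 0.160). It was also lost with a pseudocount of 0.1 (adjusted p = 0.0532), without the filter on low values (adjusted p = 0.0629) and at a mean value of 10 or more (adjusted p = 0.0585). Of 9 atrial markers Gja5 and Myl4 (-0.35) fell and Sln (-1.27) and Myl7 (-0.25) did not pass, with 3 down when adjusted over the list alone (list median -0.35; camera adjusted p = 0.0158; adjusted p = 0.459 with an estimated correlation; lost without vehicle 2, adjusted p = 0.142).

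Genes of fetal and hypertrophic growth went both ways. Of 16 tested 5 rose and 6 fell, with 7 down when adjusted over the list alone (camera adjusted p = 0.849; median -0.05, mean 0.02, direction down). Gdf15, Rcan1 (0.70), a calcineurin target, and Acta1 (0.28) rose, and Tgfb2 (-0.62), Myh7 and Ankrd1 (-0.29) fell. The natriuretic peptide genes Nppa (0.03, limma adjusted p = 0.857) and Nppb (-0.05, limma adjusted p = 0.706) did not pass. Of 26 immediate early genes 10 rose and 4 fell, with 12 up when adjusted over the list alone. Fos (0.96), Myc (0.93), Fosl2 (0.87), Nr4a1 (0.86) and Ier3 (0.66) rose, and Arc (-1.26), Srf and Dusp5 (-0.64), a phosphatase of ERK, fell. The genes of the list had a median of 0.24 (camera adjusted p = 0.00603; adjusted p = 0.459 with an estimated correlation). It was lost without vehicle 1 (adjusted p = 0.177) and without TMP195 2 (adjusted p = 0.0519). Of 24 TGF beta and BMP response genes 5 rose and 5 fell (6 and 6 when adjusted over the list alone; camera adjusted p = 0.801). Tgif1 (0.89) and Inhba (0.88) were higher, and Tgfb2, Bmp7 (-0.64) and Bmp4 (-0.60) were lower. This list had a median of 0.02, a mean of -0.04 and the direction up, and its median was -0.00 with scaling by library total.

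Some interferon stimulated genes fell, and inflammatory genes went both ways. Of 34 interferon stimulated genes 7 fell, 0 rose and 27 did not pass the test, also when adjusted over the list alone. Irf7, a transcription factor that amplifies the interferon response, fell to 0.369 times its vehicle level (limma adjusted p = 2.90e-08). Mx2 (-0.84), Parp14 (-0.75) and Cxcl10 (-0.66) fell, and Isg15 (-0.27) and Ifit1 (-0.50) did not pass. The count was 3 without the filter on low values, where Mx2 was lost (adjusted p = 0.0590), and 5 with a pseudocount of 0.1 or with the replicate number as a block. Genes of the list had a median of -0.43 (camera adjusted p = 0.00419; adjusted p = 0.413 with an estimated correlation). Of 26 inflammatory NF-kB genes 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.730), but only 1 rose with scaling by library total or without the filter on low values. Ccl2 (0.35) and Cxcl1 (0.44) were higher and Cxcl12 (-0.74) and Csf1 (-0.36) were lower. Of 18 hypoxia genes 2 rose and 3 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.877; median -0.04, mean -0.01, direction up). Vegfa (0.74) and Bnip3 (0.59) rose and P4ha2 (-0.76) fell.

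Some genes of translation and of protein turnover rose, and most did not pass the test. Of 36 cytosolic ribosomal protein genes 16 rose, 0 fell and 20 did not pass the test, and 22 rose when adjusted over the list alone. Without the filter on low values 8 of 37 rose, and without TMP195 2 the list median was 0.11. Rpl4 (0.42), Rps14 (0.36) and Rpl3 (0.29) were among them, and the list median was 0.19 (camera adjusted p = 2.23e-07; adjusted p = 0.413 with an estimated correlation). These genes have many processed pseudogenes, so their values are uncertain where fragments were divided among copies. Of 32 lysosome and autophagy genes 9 rose, Gusb (-0.64) fell and 22 did not pass, with 11 up when adjusted over the list alone. Gabarapl1 (0.89), an autophagosome protein, Bnip3, and the muscle ubiquitin ligases Fbxo32 (0.50) and Trim63 (0.39) rose, and Map1lc3b (-0.06) and Lamp1 (-0.02) did not pass. All genes of the list had a median of 0.16, and of 0.09 without TMP195 2 (camera adjusted p = 0.00149; adjusted p = 0.244 with an estimated correlation). Over all groups, camera called 22 of 38 lists with its preset correlation of 0.01 and 0 of 38 with the correlation estimated from these 4 libraries. The second mode rests on 2 residual degrees of freedom, which leaves few lists able to pass. NRF2 targets (estimated correlation -0.029) and cell cycle genes (-0.017) lost their calls too, so the loss is not a measure of correlation. Estimates reached 0.315 for TCA cycle genes, above the preset value, so neither count settles which lists moved.

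**Figure D3:**
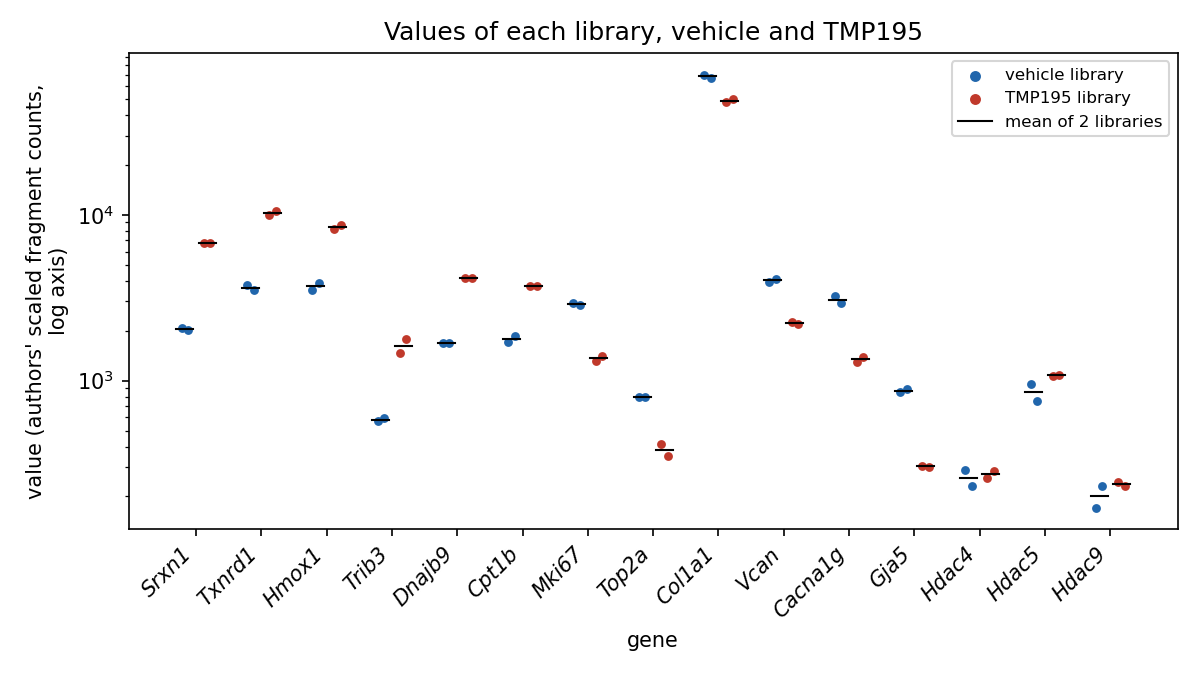
Each point is the value of a library (the authors' scaled fragment counts, log axis) for 15 named genes, blue for vehicle and red for TMP195, with a black bar at the mean of 2 libraries. The libraries of the treatments lie apart for the first 12 genes and overlap for Hdac4.

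The deposited tables also hold the authors' own comparison. The authors' deposited table lists 594 genes as higher and 623 as lower with TMP195, at unadjusted p up to 0.0504, with median ratios of 1.32 and 0.688. Srxn1 has a ratio of 3.29, Txnrd1 of 2.82, Mki67 of 0.471 and Col1a1 of 0.713 in the authors' deposited table. Of the 590 genes of the first list that were tested here, limma called 441 higher, and of the 621 of the second it called 459 lower, with 0 called in the opposite direction in either list. Limma called a further 819 genes higher and 854 lower that those lists do not hold. Of 10673 genes in the authors' deposited table, there are 1206 that have a p under 0.05, where chance gives 531. None of them stays under 0.05 after Benjamini-Hochberg adjustment of the authors' p-values, the smallest being 0.204. Both sets of calls rest on the same 4 libraries and are not independent of each other.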

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

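The filters at a mean value of 10 or 100 were chosen after seeing the data. No gene called by limma with the main settings changed sign under any setting, which is weak evidence of stability. Of the 1260 higher and 1313 lower genes, 2566 had both TMP195 libraries on the same side of both vehicle libraries. Leaving out a library could not reverse those. Scaling by library total moved the median of all genes only from -0.006 to -0.032. Across the settings that kept all 4 libraries, limma called 942 to 1386 genes higher and 1007 to 1479 lower. Scaling by library total gave 1099 higher and 1444 lower, and limma-voom 1137 and 1479. Leaving out 1 library, with the lone library of its group assumed to vary like the other group, gave 0 to 322 genes higher and 0 to 406 lower. The authors' calls found again ranged from 0 to 169 for higher and 0 to 253 for lower genes. These fits had 1 residual and 1.93 to 4.83 prior degrees of freedom, and their smallest adjusted p ran from 0.00626 to 0.183. Restricted to a mean value of 100 or more, where the prior degrees of freedom were infinite and the trend across genes replaced the spread of each gene, they called 971 to 1086 higher, of which 854 to 945 were also called with all genes and all 4 libraries, and 944 to 1082 lower, of which 867 to 975 were. The NRF2 target list lost its call with an estimated correlation in camera (adjusted p = 0.168), as did the other 21 lists called. Its median of 0.38 does not depend on that correlation. The labels do not say whether equal numbers pair the libraries. No strong shared effect of the number was seen: the differences between libraries 1 and 2 correlated at -0.063 between the treatments over 8235 genes. With the replicate number as a block, 1193 genes were higher and 1266 lower, 1174 and 1250 of them shared with the fit without it. The block ended the call of TCA cycle genes (adjusted p = 0.0536) and added p53 target genes (adjusted p = 0.0478). Of the genes named by the rule, the block, scaling by library total and limma-voom each ended 2 calls, a pseudocount of 0.1 ended 3 and no filter ended 7. Leaving out a library ended 53 to 138. The smallest log2 fold change called, over genes of any value, was 0.189 in size, and the effect of depth was not tested. The alternatives that need raw counts, DESeq2 and edgeR with other size factors, were not run, because the deposited values are scaled estimates and partly fractional. Most of them could be turned back into whole fragments, and a count test on those was not tried.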

Other observations

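The symbol families, the single gene Gsta5 and the length tests of respiratory chain and cardiac transcription factor genes were chosen after the results were seen.

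Replication-dependent histones, translation factors and secretory pathway genes stood out when genes were grouped by the letters that begin their symbols. Of 144 such families with 10 or more tested genes, 8 held more increases or more decreases than other genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted over 288 tests). The test treats genes as independent, which members that vary together or share sequence are not. A family of high values is also more easily called. Genes whose symbols begin with Arhgap were lower in 10 of 24 and higher in 1 (adjusted p = 0.00262), and the other families called are named below. Histone genes fell: 17 of 23 were lower and 0 higher (adjusted p = 2.57e-10, median -0.93), among them Hist1h1b (-1.56) and Hist2h3c2 (-1.38). Histone genes have near-identical copies, so single members are uncertain. Kinesins were lower in 12 of 27 and higher in 2 (adjusted p = 3.26e-04). Kif23 (-1.24), Kif18b (-1.12), Kif15 (-1.09), Kif13a, Kif26a and Kif26b were among those that fell, and Kif5b (0.26) and Kif16b rose. Symbols that begin with Col, mostly collagens, were lower in 12 of 25 and higher in 0 (adjusted p = 1.49e-04), with Col14a1 (-0.45) and Col11a1 (-0.56) outside the matrix list.

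Genes whose symbols begin with Eif, mostly of translation initiation, rose in 18 of 52 (adjusted p = 1.19e-04), with Eif2b3 (0.89), Eif1a (0.80) and Eif2s2 (0.55) among them. Eif4ebp1, which encodes the translation repressor 4E-BP1 and is a known ATF4 target, rose as well (0.63). The kinases Eif2ak2 (-0.48) and Eif2ak4 (-0.33), known as PKR and GCN2, were the 2 that fell. Genes whose symbols begin with Sec, which have various parts in the secretory pathway, rose in 10 of 25 (adjusted p = 0.00262), led by Sec23b (0.64), Sec61b (0.62) and Sec61a1 (0.61), while Sec16b (-0.54) and Sec24b (-0.24) fell. Symbols that begin with Rpl (19 of 46 higher, adjusted p = 3.34e-06) and Rps (13 of 39, adjusted p = 0.00262) rose as well, the latter with a few kinase genes such as Rps6kc1. The cytosolic ribosomal protein list had an estimated correlation of 0.289 and was not called by camera with it (adjusted p = 0.413). The independence that Fisher's exact test assumes is thus doubtful for these genes. The median of each of these families kept its sign with scaling by the median of ratios, by library total and with limma-voom. These settings moved the median of all genes little (from -0.006 to -0.032 with library total), so a change of sign was hardly possible. The glutathione transferase Gsta5 was listed at 0.000329 and 9.67e-05 in the vehicle libraries and at 55.0 and 27.4 in the TMP195 libraries. Its relatives Gsta2 (log2 fold change 1.13), Gsta1 (0.37) and Gsta3 (-0.39) differed from it. These genes share long stretches of sequence, so how fragments were divided among them is uncertain and no fold change is given for Gsta5.

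Fibroblast, matrix and smooth muscle genes were lower with TMP195. A smaller share of fibroblasts as the only change would lower their markers by a common factor, if each marker came from fibroblasts alone. The log2 fold changes of 10 markers with a vehicle mean of 100 or more differed beyond their errors. Cochran's Q against a chi-square distribution gave p = 4.05e-10, with the markers treated as independent. This argues against a common factor alone and cannot exclude fewer fibroblasts beside other changes. Dcn (-0.06) and Ddr2 (-0.05) stayed near 0 while Col1a1 (-0.49) and S100a4 (-0.73) fell. Removing the trend of fold change with relative gene length left the median of the fibroblast markers at -0.443 (SE 0.143) against -0.466 before, which argues against length as its source. An effect of TMP195 on expression within fibroblasts or myofibroblasts stays open as a hypothesis, with or without fewer fibroblasts or fewer dividing cells. Bulk RNA cannot assign it to a cell type.

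With TMP195 16 of 36 ribosomal protein and 9 of 38 respiratory chain genes rose slightly, and 9 of 32 ion channel and 12 of 23 cardiac transcription factor genes fell. Short genes leaned up and long genes down, with a Spearman correlation of -0.153 between log2 fold change and relative length across 10253 genes, which are not independent replicates. After removing that trend, the cardiac transcription factor median was -0.253 (SE 0.10) against -0.255 before, which argues against length for that list. The ribosomal median was 0.112 (SE 0.0261) against 0.188 before, and the respiratory chain median 0.0526 (SE 0.0251) against 0.107. The ion channel median, over the 30 of 32 genes with a length, was -0.14 (SE 0.11) against -0.20. Each was past the mark set for judging length, about midway to no change, by less than its SE. What part of these 3 shifts length gives thus cannot be told. The ribosomal median stayed above its SE, but that SE treats genes as independent. The list had an estimated correlation of 0.289, so the SE is likely too small. Whether length accounts for all of that rise thus cannot be told either. An effect of TMP195 stays open and was not tested separately.

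NRF2 target and integrated stress response genes rose together. The median of the NRF2 list, over the 30 genes with a length, was 0.402 (SE 0.142) after removing the length trend and 0.396 before. Slc7a11 is the only gene in both lists, and without it 18 of 31 NRF2 genes rose and 1 fell. The NRF2 list was not called with an estimated correlation (adjusted p = 0.168). The length test argues against length as the source of the NRF2 increase, and an effect of TMP195 on both programs remains as a hypothesis found and tested on the same data. Whether inhibition of class IIa enzymes or another action of the compound produced it was not tested, since the design has a single compound and dose.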
